A study of Ovis aries with 36 samples.

How the data were processed

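Messenger RNA was sequenced from the hypothalamus, the pars tuberalis and the pineal gland of 12 adult rams of the Spanish breed Rasa Aragonesa. The pineal gland secretes melatonin at night, the pars tuberalis is the part of the pituitary that reads the melatonin signal, and the hypothalamus holds the neurons that drive the reproductive axis. Per the labels, 6 rams were sexually active and 6 were not active (called inactive here), and every ram gave 1 library per tissue. The 36 libraries fall into 6 groups of 6 by tissue and state. Animals 1 to 6 were active and animals 7 to 12 were inactive, so the replicates of a group are different animals.

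Per the labels' protocols, tissue was frozen in liquid nitrogen, RNA was isolated with a kit for lipid-rich tissue, and stranded messenger RNA libraries were read from both ends for 151 bases on an Illumina NovaSeq. The adaptors carried unique molecular identifiers. Per the submitters' processing notes, FastQC, STAR 2.7.8a, HTSeq and edgeR were used, with no role and no other version stated. The genome build, the annotation release, the strand setting of the counting step, the treatment of reads that map to several genes, and any collapsing of reads by molecular identifier are not given in the sources used here. Near-identical gene copies and overlapping genes are therefore uncertain. Reads that are copies of 1 molecule can also still be counted, so counting intervals cover counting error only.

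The authors deposited raw counts per gene, as whole numbers that were not normalised, for 26478 Ensembl sheep gene IDs in 36 libraries. Totals ran from 19251952 to 72951491 counts per library, and 3860 IDs had no count in any library. All columns matched 1 labelled sample each. Between libraries of 1 group the lowest chi-square per degree of freedom over 90 pairs was 35.7, where sampling noise alone gives about 1. No library was therefore a copy of another of its group, and pairs from different groups were not compared in this way. The deposited counts do not pair IDs with gene names, and 0 of the 26478 IDs matched a symbol in the reference gene table used here. For this reason the 33 lists of gene symbols and cell type markers fixed beforehand were not used here, and the planned gene list tests were not run.

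Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's filter with its default minimum count of 10 and the 6 groups as its design, which left 16773 genes and removed 9705. Libraries were scaled by trimmed mean of M values (TMM), and levels are given as TMM-scaled counts per 1000000 counts of the library (CPM). All 36 libraries entered 1 quasi-likelihood fit with robust spread, 1 mean per group and 30 residual degrees of freedom, because the design text describes state and tissue as factors of a single design. State was tested within each tissue, and each pair of tissues was compared with both states weighted equally. A test on 2 degrees of freedom asked whether the effect of state was equal in the 3 tissues. For state over the tissues, the 3 libraries of an animal were summed, which gave 12 animals and 17232 tested genes. Raw counts were summed without equalising depth, so a tissue's share of a sum follows the depth of its library. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors (SE) were taken as the absolute log2 fold change over the square root of F. Differences of single values per library were tested by exact two-sided permutation of the 12 animals.

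The groups, tests, named-gene rule and alternatives were fixed before the data were examined, except where stated. For genes without a name, the rule allowed at most 2 IDs in each direction per comparison. It did not say how to pick those IDs, so the choice given next was not fixed by it. For state these were the called genes with the lowest p, or the genes with the lowest p where none was called. For tissues they were the called genes with the largest fitted fold change among those with a mean of at least 10 CPM in either tissue. Tissue-restricted gene sets were defined from these libraries after the data were seen, as genes with a median of at least 20 CPM in 1 tissue and at least 50 times the median of both others. A library's level for such a set is the median over its genes of CPM as a percent of the median in the set's own tissue.

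The labels give the 3 libraries of a ram the same animal number, so the numbers pair the tissues. Over 12377 genes, the deviations from the group mean correlated between libraries of the same animal at a median of 0.026 for hypothalamus and pars tuberalis, 0.13 for hypothalamus and pineal gland, and 0.2 for pars tuberalis and pineal gland. The state comparisons set different animals against each other and cannot take an animal term within a tissue. Tissue and interaction tests were repeated with the animal as a block.

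The scripts were tested on simulated data drawn from the means, library sizes and spread of the real libraries. Genes were drawn independently, so variation shared by many genes is absent and false calls in real data can be more. Changed genes for state were drawn among those above 1 CPM in the tissue, so the detection rates do not cover lower genes. With 16698 genes and 100 changed genes per fold, the hypothalamus state test on 36 libraries called 26 genes changed 1.5-fold, 61 changed 2-fold, 95 changed 4-fold and 98 changed 8-fold, all with the right sign. In the same sets it also called 103 of 32993 unchanged genes, against 17 in the pars tuberalis and 14 in the pineal gland. In the pars tuberalis the test called 62 and in the pineal gland 60 of the 100 genes changed 2-fold. In 10 simulated sets with no state effect the hypothalamus test made 1 to 20 false calls (median 5), the pars tuberalis test 0 to 1 and the pineal test 0 to 3. The same hypothalamus test fitted on its own 12 libraries made 0 in each set, but it also called fewer changed genes, 5 of 100 at 1.5-fold and 40 at 2-fold. The spread between animals differed between tissues, with a common biological coefficient of variation of 0.404 in the hypothalamus, 0.32 in the pars tuberalis and 0.323 in the pineal gland.

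Alternatives were RLE in place of TMM scaling, no filter on low counts, a non-robust spread, and a fold minimum (1.5 for state, 2 for tissue). Others were fits of 1 tissue alone, limma 3.58.1 voom with the animal as a random block, voom with library quality weights, DESeq2 1.42.0, an additive fit for state over tissues, and every animal left out in turn. Fits without single libraries in doubt, a fit with the level of pars tuberalis genes as a covariate, and voom without the random term were added after the data were seen.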

Results

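Gene expression was measured by RNA sequencing in the hypothalamus, pars tuberalis and pineal gland of 12 adult rams, of which 6 showed sexual activity and 6 did not (inactive). The series asks which genes differ with sexual behaviour in these tissues, with state as the main factor and tissue as the second. Each of the 6 groups held 6 libraries from 6 animals. Depth, in units of 1000000 counts, ran from 19.25 to 44.28 in the hypothalamus (median 30.14), from 22.56 to 35.44 in the pars tuberalis (median 28.49) and from 25.24 to 72.95 in the pineal gland (median 40.38). In the pars tuberalis, active animals had a depth of 31.14 ± 3.54 (SD, n = 6) and inactive animals one of 26.77 ± 3.16 (SD, n = 6) in the same unit. That difference had a two-sided exact permutation p of 0.0498, which was 0.149 after Benjamini-Hochberg adjustment over the 3 tissues (0.645 in both other tissues). Gene IDs stand without names throughout, because the files do not pair IDs with names.

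Tissue set the main structure of the data. The first principal component held 45% of the variance and parted the pars tuberalis from the pineal gland, and the second held 31.9% and parted the hypothalamus from both. Over the 16773 tested genes, tissue accounted for a median of 60.6% of a gene's variance and state for a median of 0.608%. Between them, the 3 tissue comparisons called 3326 genes higher in the hypothalamus than in both other tissues, 725 of them at least 4-fold against each. The corresponding sets held 3887 genes for the pars tuberalis (549 at least 4-fold) and 3093 for the pineal gland (612 at least 4-fold). Genes below both other tissues numbered 2632 in the hypothalamus, 3971 in the pars tuberalis and 2674 in the pineal gland. No tissue comparison called 1760 genes (10.5%), and all 3 called 5877 (35%).

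**Figure D1:**
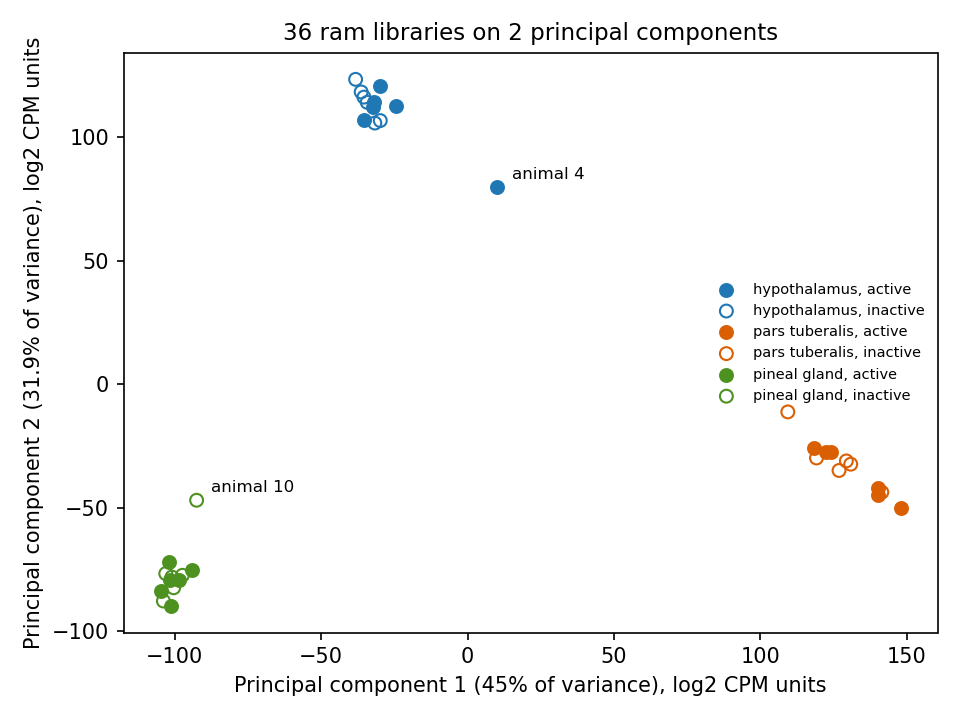
Each point is 1 of the 36 libraries, placed by its scores on the first 2 principal components of log2 CPM (45% and 31.9% of the variance); colour gives the tissue, and filled and open points give active and inactive rams. Libraries group by tissue, and the hypothalamus library of active animal 4 and the pineal library of inactive animal 10 lie apart from their tissues.

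The 35 genes restricted to the hypothalamus, 43 to the pars tuberalis and 69 to the pineal gland gave a check of each library's tissue. Their median levels in their own tissue had medians of 140.2, 50.62 and 230.3 CPM. Every library held its own tissue's genes at 55.9% or more of the tissue median. Pineal genes stood at no more than 0.266% in any hypothalamus library and 0.191% in any pars tuberalis library. Pars tuberalis genes stood at 17.1% in the hypothalamus library of active animal 4, where the next hypothalamus library had 1.99% and the median was 0.372%. Hypothalamus genes stood at 8.95% in the pineal library of inactive animal 10, where the next pineal library had 1.57% and the median was 0.696%.

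**Figure D2:**
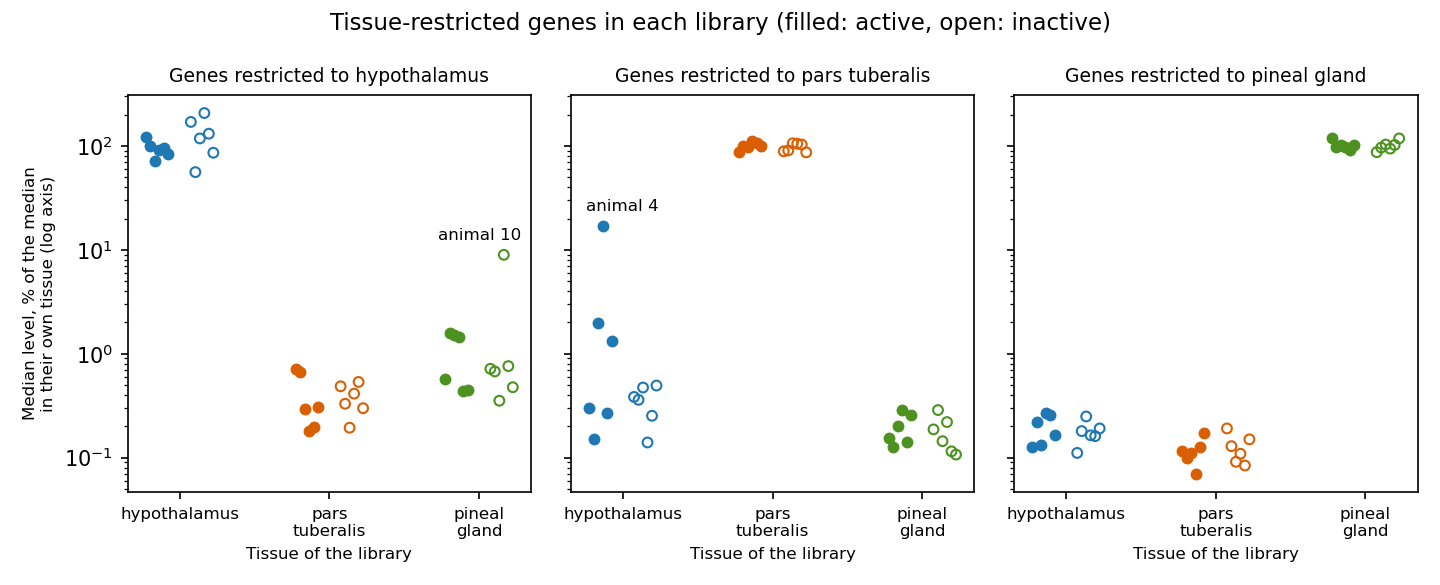
Each point is a library, and each panel shows 1 set of tissue-restricted genes; the vertical log axis is the median level of the set as a percent of its median in its own tissue, with active rams filled and inactive rams open. The library of animal 4 stands out among hypothalamus libraries for pars tuberalis genes (17.1%), and that of animal 10 among pineal libraries for hypothalamus genes (8.95%).

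The pars tuberalis differed from the hypothalamus in 12070 of 16773 genes, 5964 higher and 6106 lower. Of these, 2437 were at least 2-fold higher and 3640 at least 2-fold lower, and 94 and 336 differed at least 32-fold. ENSOARG00020016511 had the highest level of the IDs named here, at 10900 ± 5490 CPM in the pars tuberalis and 8.53 ± 15.1 CPM in the hypothalamus (SD, n = 12 each), a log2 difference of 11.53 (SE 1.09) and a pooled ratio of 1650 (95% counting interval 1580 to 1720). Of the 2445 hypothalamus counts of ENSOARG00020016511, 855 came from active animal 6. Without that library its pooled ratio was 2420 (2300 to 2540), outside the interval with all libraries. ENSOARG00020002444 stood at 246 ± 81.2 and 0.198 ± 0.36 CPM, 12.08 higher on the log2 scale (SE 0.572). Its pooled ratio was lower, at 1550 (1200 to 2040), since the fit averages the states on the log scale and the inactive hypothalamus libraries held 1 count against 57 in the active ones. Without the hypothalamus library of animal 6 that ratio was 2200 (1610 to 3090). In the other direction, ENSOARG00020009581 had 275 ± 286 CPM in the hypothalamus and 2 counts in all pars tuberalis libraries together, both in animal 4, a pooled ratio of 52700 with a 95% counting interval of 14600 to 435000. ENSOARG00020005236 had 214 ± 185 CPM in the hypothalamus and 0.0798 ± 0.067 in the pars tuberalis, a log2 difference of -11.32 (SE 0.926). For these 4 IDs every library of the higher tissue exceeded every library of the lower one. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, their adjusted p values ran from 2.93e-11 to 7.72e-19. With a fold minimum of 2 in the test, 4461 genes were called.

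The pineal gland differed from the hypothalamus in 10703 genes, 5202 higher and 5501 lower. At least 2-fold differences numbered 2098 higher and 2926 lower, and 180 and 224 genes differed at least 32-fold. ENSOARG00020005641 stood at 2570 ± 984 CPM in the pineal gland and 0.0421 ± 0.0612 in the hypothalamus (SD, n = 12 each), 15.85 higher on the log2 scale (SE 0.408). ENSOARG00020015837 stood at 1450 ± 268 CPM in the pineal gland against 4 counts in all hypothalamus libraries, a pooled ratio of 133000 (95% counting interval 51800 to 487000, and 253000 without the hypothalamus library of animal 6). ENSOARG00020005236 was lower in the pineal gland, at 0.161 ± 0.143 against 214 ± 185 CPM, with a log2 difference of -10.28 (SE 0.857). ENSOARG00020018777 had 8211 counts in the hypothalamus and 4 in the pineal gland, a pooled ratio of 2730 (1070 to 10000), which was 1430 without the hypothalamus library of animal 8 and 4990 without the pineal library of animal 6. Its hypothalamic level ran from 0 in 3 libraries to 180 CPM, so for it and for ENSOARG00020005236 single hypothalamus libraries lay within the pineal range. Adjusted p for the 4 IDs ran from 6.25e-07 to 1.36e-28 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With a fold minimum of 2, 3557 genes were called.

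The pineal gland differed from the pars tuberalis in 11824 genes, 6158 higher and 5666 lower. At least 2-fold differences numbered 3361 higher and 2785 lower, and 347 and 266 genes differed at least 32-fold. ENSOARG00020005641, at 2570 ± 984 CPM in the pineal gland, had 3 counts in all pars tuberalis libraries, a pooled ratio of 333000 (95% counting interval 114000 to 1620000, and 918000 without the pars tuberalis library of animal 6). ENSOARG00020008252 had 833 ± 238 CPM and 1 count, a ratio of 329000 (59000 to 1.3e+07). Higher in the pars tuberalis were ENSOARG00020022677, at 132 ± 84.7 CPM against 3 counts in the pineal gland (ratio 21200, 7250 to 103000), and ENSOARG00020015174, at 3190 ± 1090 CPM against 0.824 ± 2.01, a log2 difference of -13.32 (SE 1.36) and a pooled ratio of 2970 (2720 to 3240). Of the 517 pineal counts of ENSOARG00020015174, 398 came from active animal 4, and without that library the pooled ratio was 11300 (9470 to 13700). For these 4 IDs no library of the lower tissue reached a library of the higher one. Adjusted p ran from 2.48e-10 to 1.75e-26 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 4615 genes were called with a fold minimum of 2.

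In the hypothalamus, 16 of 16773 genes were called by state, 11 higher and 5 lower in active rams. ENSOARG00020026374 averaged 4.19 ± 9.38 CPM in active and 0.0307 ± 0.036 in inactive rams (SD, n = 6 each), and ENSOARG00020004662 averaged 16.0 ± 34.5 and 0.404 ± 0.563 CPM. Both means rested on active animal 4, at 23.3 and 86.3 CPM, where the next active animals had 1.14 and 6.71, and without animal 4 their log2 differences were 3.4 and 2.42. Lower in active rams were ENSOARG00020016201, at 0.792 ± 0.487 against 6.09 ± 3.70 CPM, and ENSOARG00020006027, at 22.5 ± 6.77 against 63.2 ± 31.4 CPM. ENSOARG00020006027 was the only called gene whose groups did not overlap, at 9.21 to 27.9 CPM in active and 36.2 to 118 CPM in inactive rams. Of all tested genes 19 (0.113%) had groups apart in this tissue, where chance gives 0.216%.

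The log2 differences were 7.08 (SE 1.24) for ENSOARG00020026374 and 5.57 (SE 1.08) for ENSOARG00020004662. They were -3.0 (SE 0.52) for ENSOARG00020016201 and -1.49 (SE 0.277) for ENSOARG00020006027. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, their adjusted p values were 0.0187, 0.03, 0.0187 and 0.03 in that order. These can be too low, since this test made more false calls in simulated sets than its threshold allows. Of the 11 genes higher in active rams, 8 had a median in the pars tuberalis at least 10 times that in the hypothalamus, and all 8 were highest in animal 4, the hypothalamus library with pars tuberalis genes at 17.1%. ENSOARG00020026374 had 35.7 ± 8.23 CPM in the pars tuberalis and ENSOARG00020004662 had 238 ± 31.4 (SD, n = 12). Of the 5 lower genes, 1 was of this kind, ENSOARG00020016201 with 40.5 ± 13.1 CPM in the pars tuberalis. The level of pars tuberalis genes in hypothalamus libraries had a mean log2 percent of -0.144 in active and -1.63 in inactive rams, with a two-sided exact permutation p of 0.197 (adjusted p 0.946 over 9 such comparisons).

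The count of 16 depended on single animals. It was 0 without animal 4, 10 or 11 (1356, 1035 and 1465 genes at an unadjusted p under 0.05), then 2 without animal 9, 4 without 7, 5 without 3, 6 without 12, 25 without 2, 31 without 6, 32 without 5, 37 without 1 and 54 without 8. It was 0 when only the hypothalamus library of animal 4 was left out (1397 at an unadjusted p under 0.05) and 5 without that of animal 10. The fit of the 12 hypothalamus libraries alone called 0 genes (711 at an unadjusted p under 0.05), and DESeq2 called 140 (91 higher, 49 lower). Voom with the animal as a random block called 1, which was ENSOARG00020006027 (log2 difference -1.42, adjusted p 0.022 by limma with Benjamini-Hochberg adjustment). Over the 26 alternatives its log2 difference ran from -1.62 to -1.22 and its adjusted p from 0.000189 to 0.999. The log2 difference of ENSOARG00020004662 ran from 0.271 to 6.48. Without the hypothalamus library of animal 4 DESeq2 called 75, of which 53 were among the 140. At an unadjusted p under 0.05 the 36-library fit had 1565 genes (9.33%). The balance of directions among edgeR's calls also moved with the animal left out. There were 0 higher and 4 lower without animal 7, 24 and 30 without 8, and 22 and 3 without 2.

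**Figure D3:**
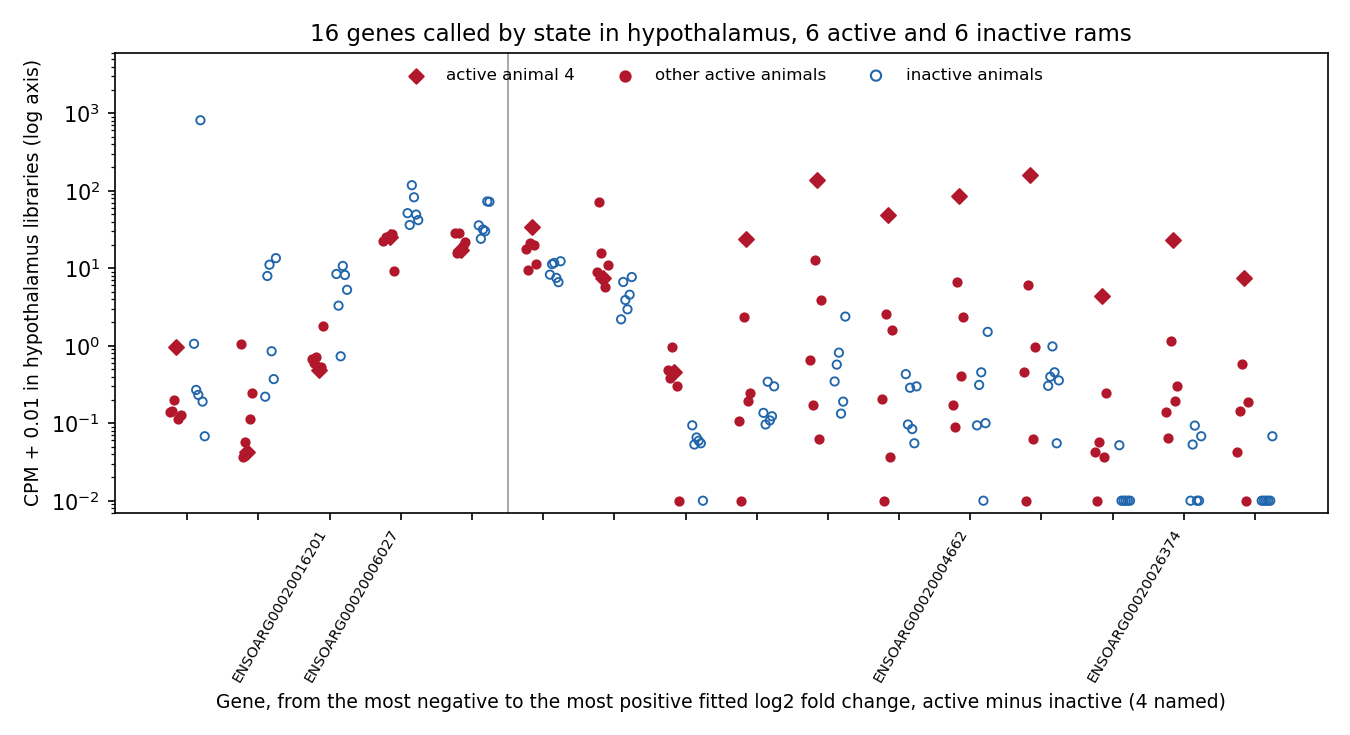
Points are CPM in single hypothalamus libraries on a log axis with a small constant added, for the 16 genes called by state (11 higher in active rams right of the grey line, 5 lower left of it); filled points are active and open points inactive rams, and diamonds mark active animal 4. Animal 4 is the highest library for 9 of the 11 genes called higher, and ENSOARG00020006027 alone shows no overlap between states.

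In the pars tuberalis, edgeR's quasi-likelihood test called 0 of 16773 genes by state, and 593 (3.54%) had an unadjusted p under 0.05. DESeq2 called 1 gene, ENSOARG00020025419 (log2 difference -5.85, adjusted p 0.00301 by DESeq2 with Benjamini-Hochberg adjustment, and 0.00301 to 1 over the alternatives). This ID averaged 0.0573 ± 0.0707 CPM in active and 3.36 ± 5.94 in inactive rams (SD, n = 6 each), with 15.4 CPM in animal 11 and 2.11 in the next. In edgeR's test it had a log2 difference of -5.75 (SE 1.25) and an adjusted p of 0.945. Over the alternatives its log2 difference ran from -6.64 to -3.92. ENSOARG00020017045 averaged 1.66 ± 0.65 and 3.77 ± 1.83 CPM, a log2 difference of -1.18 (SE 0.291). ENSOARG00020023371 averaged 3.23 ± 1.33 in active and 1.51 ± 0.455 CPM in inactive rams, a log2 difference of 1.09 (SE 0.25), and ENSOARG00020017980 averaged 1.28 ± 1.87 and 0.168 ± 0.0871 CPM (2.92, SE 0.748). The active mean of ENSOARG00020017980 rested on animal 1, at 4.9 CPM against 1.72 in the next, and its log2 difference without animal 1 was 1.74. ENSOARG00020017045, ENSOARG00020023371 and ENSOARG00020017980 each had an adjusted p of 0.967 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For 12107 of 16754 genes (72.3%) the 95% interval of the state effect excluded a 2-fold difference in either direction. The 43 pars tuberalis genes had a mean log2 percent of 6.65 in active and 6.59 in inactive rams (two-sided exact permutation p 0.448, adjusted p 0.946). Without animal 6 edgeR called 1 gene, ENSOARG00020023371, at an adjusted p of 0.0254 by its quasi-likelihood test with Benjamini-Hochberg adjustment (0.0254 to 1 over the alternatives), and without any other animal it called 0.

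In the pineal gland, edgeR's quasi-likelihood test called 0 of 16773 genes by state, and 326 (1.94%) had an unadjusted p under 0.05. DESeq2 called 20, of which 2 were higher and 18 lower in active rams. ENSOARG00020025044 averaged 0.261 ± 0.185 CPM in active and 3.13 ± 5.46 in inactive rams (SD, n = 6 each), and ENSOARG00020008760 averaged 0.187 ± 0.0651 and 2.55 ± 4.81 CPM. Both were highest in inactive animal 10, at 14.2 and 12.3 CPM, where the next inactive animals had 1.91 and 0.929. That library held hypothalamus genes at 8.95%, and the 2 IDs averaged 16.1 ± 16.9 and 4.77 ± 2.87 CPM in the hypothalamus (SD, n = 12). ENSOARG00020015585 averaged 89.4 ± 190 CPM in active and 0.713 ± 0.809 in inactive rams, with 476 CPM in animal 4 and 39 in the next. It averaged 1570 ± 1230 CPM in the pars tuberalis (SD, n = 12) and was highest in animal 4 in the hypothalamus too, at 697 CPM, while the pineal library of animal 4 held pars tuberalis genes at 0.285%. ENSOARG00020022989 averaged 261 ± 186 and 139 ± 13.8 CPM, with 621 CPM in active animal 5 and 302 in the next. The log2 differences of the 4 IDs were -3.63 (SE 0.783), -3.73 (SE 0.823), 6.96 (SE 1.67) and 0.91 (SE 0.243) in that order. They were -1.87 and -1.61 without animal 10 for the first 2, 4.07 without animal 4 for ENSOARG00020015585 and 0.436 without animal 5 for ENSOARG00020022989. Their adjusted p was 0.475 for the first 3 and 0.539 for ENSOARG00020022989 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The first 3 were among DESeq2's 20, at adjusted p 0.00171, 0.00123 and 0.000111 with Benjamini-Hochberg adjustment (over the alternatives up to 1 for each, and down to 1.24e-05 for ENSOARG00020015585 by DESeq2 without the pineal library of animal 10). For 12929 of 16762 genes (77.1%) the 95% interval of the state effect excluded a 2-fold difference. The 69 pineal genes had a mean log2 percent of 6.66 in active and 6.64 in inactive rams (two-sided exact permutation p 0.788, adjusted p 0.946). Without the pineal library of animal 10, edgeR still called 0 genes and DESeq2 called 5 (2 higher, 3 lower), all among its 20.

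Summed over the 3 tissues of each animal, edgeR's quasi-likelihood test called 0 of 17232 genes by state, with 803 (4.66%) at an unadjusted p under 0.05. Unequal depth gives the tissues unequal shares of the sums, which can add to the spread between animals, so this 0 does not exclude an effect. DESeq2 on the same sums called 11 genes, all lower in active rams, and voom on the 36 separate libraries with the animal as a random block called 2. The genes with the lowest p among those lower in active rams were ENSOARG00020010269, with a log2 difference of -0.89 (SE 0.163), and ENSOARG00020007456, with -0.77 (SE 0.143). In the hypothalamus ENSOARG00020010269 averaged 14.9 ± 3.82 CPM in active and 31.3 ± 6.69 in inactive rams, and ENSOARG00020007456 averaged 125 ± 33.8 and 208 ± 44.9 CPM (SD, n = 6 each). Means of both were lower in active rams in the pars tuberalis and pineal gland too, at 4.81 ± 2.5 against 6.55 ± 2.6 and 5.48 ± 1.25 against 7.45 ± 1.51 CPM for the first. ENSOARG00020019510 differed by 1.03 (SE 0.245) and ENSOARG00020023921 by 0.46 (SE 0.113) in the other direction. The 4 IDs each had an adjusted p of 0.933 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 called ENSOARG00020010269 and ENSOARG00020007456, at adjusted p 0.00339 and 0.00771 with Benjamini-Hochberg adjustment (up to 1 for both over the alternatives).

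The effect of state was not shown to differ between the tissues. The interaction test called 0 of 16773 genes, with 543 (3.24%) at an unadjusted p under 0.05 by edgeR's quasi-likelihood test, and 0 with the animal as a block (340 at an unadjusted p under 0.05). DESeq2's likelihood ratio test called 1, ENSOARG00020004410, at an adjusted p of 0.0477 with Benjamini-Hochberg adjustment (0.679 by edgeR's test), an ID singled out after its values were seen. It is among the 9 genes called higher in active hypothalamus and highest in animal 4, at 7.42 CPM there and 0.571 in the next library.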

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

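The tests of the library of animal 4 on the called genes, of misassigned reads, of unequal spread and of splits at an unadjusted p were chosen after the results were seen. Counts of called genes over other splits of the animals, and the test for whole tissue at 1 proportion, were set out before their results were seen.

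Of 54 sets of 6 libraries, 10 held a library far from the others of its group. The rule's chance rate of about 1 in 20 holds for normally spread values only. Several of these sets are small counts or percents, so the 10 cannot be set against that rate. The hypothalamus library of active animal 4 held pars tuberalis genes at 17.1%, against 0.15% to 1.99% in the other active rams. It also held 34 genes above 5 CPM and over 10 times the next library of its tissue, against 0 to 9 in the others. The hypothalamus library of inactive animal 10 had 10 such genes against 0 to 1, and the pars tuberalis library of active animal 1 had 7 against 0 to 1. The pineal library of active animal 1 had 5 against 0 to 1, and pineal genes at 119% against 92.1% to 102%. The pineal library of inactive animal 10 held hypothalamus genes at 8.95% against 0.353% to 0.76%, and had 23 such genes against 0 to 1. In the hypothalamus of active animal 6, ENSOARG00020016201 stood at a log2 CPM of 0.872, above the other active rams, and ENSOARG00020006027 at 3.21, below them.

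Chance could not be excluded for the 16 genes called by state in the hypothalamus. Of 100 splits of the 12 animals into 6 and 6, 32 gave as many, and the highest other split gave 3769, which points to a structure of the hypothalamus libraries other than state. By edgeR's quasi-likelihood test that split called 0 genes in the pars tuberalis and 0 in the pineal gland (929 and 565 at an unadjusted p under 0.05). This split set animals 1, 2, 4, 5, 10 and 11 against the rest. Hypothalamus libraries of those animals held 29161663 to 44283825 counts. Those of the rest held 19251952 to 26667022 counts, except 39788360 in animal 9. On the first principal component of hypothalamus libraries alone (33.8% of variance), those animals scored -6.34 to 87.33. The rest scored -69.51 to -16.56, except 41.21 in animal 7. These values were compared afterwards. Whether depth or another property sets the sides apart was not tested. Whether pars tuberalis tissue in the hypothalamus library of active animal 4 accounts for the 8 genes higher in active rams and at least 10 times higher in the pars tuberalis stays open. Their median absolute log2 difference was 5.8 with that library (SE of single genes 0.973 to 1.51) and 2.4 without it (0.67 to 1.38), or 41.4%, but all 8 were highest in that library, so a fall decides nothing. Without it edgeR's quasi-likelihood test called 0 genes (1397 at an unadjusted p under 0.05), and DESeq2 still called 9 of the 16, 5 of the 11 higher and 4 of the 5 lower. With the level of pars tuberalis genes as a covariate the median of the 8 was 0.521, and that of the 5 lower genes 2.85 against 3.0 without the covariate. Of the 8, 6 belong to the genes whose level was the covariate and animal 4 has its highest value, so this decides nothing for them either. The tables argue against that tissue for the 5 lower genes, whose smallest absolute log2 difference was 1.02 (SE 0.2). A fall to 0 in 1 library of 6 can lower a group mean by 0.263 at most. Their median was 3.0 with the library (SE 0.2 to 1.69) and 2.89 without it (0.211 to 1.97). Among them, ENSOARG00020000496 rested on another single library, that of inactive animal 10, at 813 CPM against 1.05 in the next hypothalamus library. Pars tuberalis tissue is argued against too for ENSOARG00020008816, called higher. Its highest pars tuberalis library had 0.751 CPM and its lowest hypothalamus library 2.18, so that added tissue could not raise it. This ID was highest in active animal 2, at 72.2 CPM against 15.8 in the next hypothalamus library. Such tissue stays open for the other 2 higher genes as a pair, ENSOARG00020006589 and ENSOARG00020000738. They went from 3.05 (SE 0.61) to 3.03 (SE 0.636) and from 0.988 (SE 0.206) to 0.736 (SE 0.183), with a median at 93.4% of its value with the library. The 2 genes differed, since ENSOARG00020006589 kept 99.5% of its difference and ENSOARG00020000738, highest in animal 4, kept 74.5%. ENSOARG00020006589 had 0.448 CPM in animal 4, below animals 3 (0.951) and 1 (0.482), but its levels were low in all hypothalamus libraries. These IDs and ENSOARG00020000496 were singled out after their values were seen. The differences without the library come from a fit that kept the gene filter and scaling of all 36. Without the library edgeR's calls of these other 8 genes ended too. Their adjusted p values then ran from 0.0681 to 0.175 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The end of these calls is thus a crossing of the threshold of 0.05 and does not show that the differences rested on animal 4. For ENSOARG00020008816 a larger SE was not the reason, since its SE was 0.452 with the library and 0.451 without, and its difference rose from 2.12 to 2.29. A larger SE was not the reason for ENSOARG00020000738 either, since its SE fell from 0.206 to 0.183, and its difference fell from 0.988 to 0.736. For the others of these 8 genes, whether larger SEs or fewer low p values ended the calls was not tested. A spread wider in the hypothalamus than in the other tissues stays open for all 16, since the highest of 10 simulated sets with no state effect gave 20 calls (median 5) and the fit of the hypothalamus alone called 0 (711 at an unadjusted p under 0.05, and 140 calls by DESeq2). That fit also called fewer simulated genes changed 2-fold, 40 against 61 of 100, so its 0 does not set this apart from a real effect, and an effect of state stays open too.

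Transcripts of another tissue stood out in 2 libraries: 28 of 43 pars tuberalis genes were highest among hypothalamus libraries in active animal 4, and 32 of 35 hypothalamus genes were highest among pineal libraries in inactive animal 10. Whole pars tuberalis tissue at 1 proportion, and reads misassigned from the pars tuberalis libraries, which would carry the same mix, are argued against in animal 4, because the SD over genes of the log2 level against the pars tuberalis median was 2.82, above the 1.12 of the most uneven pars tuberalis library, with levels from 0% to 224%. In animal 10 the SD over hypothalamus genes was 1.7, within the 1.75 of the most uneven hypothalamus library, so hypothalamic tissue taken along with the pineal gland is a candidate explanation, and misassigned reads of hypothalamus libraries cannot be told apart from it because they would carry the same mix. For animal 4 a source made up differently from the 12 pars tuberalis libraries stays open, and no biological explanation was tested.

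For the 0 calls by edgeR's quasi-likelihood test in the pars tuberalis (highest other split 40), the pineal gland (262), the sums over tissues (95) and the interaction (61), the splits decide nothing, since all 100 must give at least 0. For the genes at an unadjusted p under 0.05 chance could not be excluded. Splits with at least as many numbered 40 for the hypothalamus (1565 genes, highest other 6372), 54 for the pars tuberalis (593, 3573), 94 for the pineal gland (326, 3397), 44 for the sums (803, 2934) and 71 for the interaction (543, 3011). DESeq2 called 140, 1, 20, 11 and 1 genes for the hypothalamus, pars tuberalis, pineal gland, sums and interaction. For the tissue comparisons chance was excluded: in 100 shuffles of tissue labels within animals, 1 gave as many calls as the real labels, which was the real arrangement in each of the 3 comparisons. The real counts of 12070, 10703 and 11824 stood against highest other counts of 2660, 5511 and 4778.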

How the results depend on the processing

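The fits without single libraries, with the pars tuberalis level as a covariate and with voom without a random term were chosen after the data were seen. Of 59 counts of called genes under other settings 37 stayed within 1.5 times the reported count. These 37 include state counts of 0 that stayed 0 and tissue counts, so they do not show that the hypothalamus calls were stable. Of 208 values of named genes under those settings 31 lost their call, 8 gained 1 and none changed sign. The 16 hypothalamus calls became 0 with a fold minimum of 1.5, 0 in the tissue alone, 0 with quality weights, 1 with voom and the random animal block, 1 with voom without it, 0 without the library of animal 4, 5 without that of animal 10, 0 without both, 0 with the covariate, 140 with DESeq2 and 75 with DESeq2 without the library of animal 4. The calls at unadjusted p under 0.05 in those fits ran from 412 to 1816. Leaving out 1 animal gave 0 to 54 calls in the hypothalamus, 0 to 1 in the pars tuberalis, and 0 in the pineal gland and the sums for every animal (284 to 408 and 563 to 2149 genes at an unadjusted p under 0.05). DESeq2 raised the counts of 0 to 1 in the pars tuberalis (1 also without the library of animal 7), to 20 in the pineal gland (5 without the library of animal 10), to 11 for the sums and to 1 for the interaction. For state over tissues fitted on the 36 separate libraries in place of the sums, voom with the random animal block called 2, and an additive fit that treats the 3 tissues of a ram as independent called 17 (8 higher, 9 lower). The 2 were ENSOARG00020006897 (log2 difference 1.51) and ENSOARG00020025432 (-2.78), singled out after their values were seen. A fold minimum of 2 lowered the tissue counts to 4461, 3557 and 4615, by its construction. The animal block changed no count of tissue or interaction calls by more than 1.5 times (12341, 11019, 12121 and 0). The cause of the other changes was not tested. The gene list tests, with their estimated correlation, tissue alone and fry settings, were not run. At these depths and spreads simulated 1.5-fold changes were called in 26 of 100 genes in the hypothalamus, so most effects of that size were not detectable.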

Other observations

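The comparison of animals within a state was chosen after the data were seen, and its shuffles and the test for a shared factor were set out before their results were seen. The correlations between tissues at the end carried no prediction.

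Rams of the same state differed from each other in part of their genes by more than the spread between their tissues. edgeR's quasi-likelihood test for animal, with tissue and state in the model, called 757 of 16773 genes (4.51%), and 367 of them spanned more than 2 on the log2 scale between rams of 1 state in their mean over tissues. For 8 genes, 1 ram was more than 10 times below the median level in each of its 3 tissues. With the 200 genes of lowest p taken from 2 tissues, all 12 libraries of the third correlated best with their own animal, whichever tissue was held out. The lowest correlation with the own animal was 0.74 for the hypothalamus, 0.72 for the pars tuberalis and 0.77 for the pineal gland, and the highest with another animal was 0.25, 0.29 and 0.25. These correlations are across genes, which are not independent replicates.

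Chance matching of animals is argued against, since 20 shuffles of the animal numbers within tissue and state gave at most 3 such genes (median 0). A single factor shared by many genes, such as collection day or condition of the ram, is argued against as the main source, because the first principal component of the animal means held 15.5% of their variance (highest of 100 shuffles 12.7%). Inherited differences between rams may underlie these genes, which is a hypothesis that was not tested. Of these genes 45 (6.02% of those tested on sums) had an unadjusted p under 0.05 for state over tissues.

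ENSOARG00020025419, which DESeq2 called in the pars tuberalis, had lower means in active rams in both other tissues, at 0.0787 ± 0.0788 against 1.06 ± 0.883 CPM in the hypothalamus and 0.125 ± 0.263 against 1.78 ± 1.72 CPM in the pineal gland (SD, n = 6 each). It was singled out after its values were seen. Summed over tissues it had a log2 difference of -4.62 (SE 0.977) and an adjusted p of 0.933 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

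Across 12377 genes, the state differences of 2 tissues correlated at 0.148 for hypothalamus and pars tuberalis, 0.215 for hypothalamus and pineal gland, and 0.222 for pars tuberalis and pineal gland. Other splits of the same animals gave correlations as large in 40, 18 and 21 of 100 splits, with the real one counted. The covariances were 0.0121, 0.0152 and 0.0128, against medians over splits of 0.00529, 0.0101 and 0.00324.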
